A study of Mus musculus with 24 samples.

How the data were processed

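Gene expression was measured on 24 single-colour Illumina mouse bead arrays, labelled with Cy3, from FVB mice at postnatal day 4. Per the design text, the arrays form 8 groups of 3 biological replicates: SMA mice and wild-type (WT) mice, each in the medial motor column (MMC) and the lateral motor column (LMC) of the spinal cord, the dorsal root ganglion (DRG) and the raphe. SMA is read here as spinal muscular atrophy, a disease of motor neurons caused by loss of the survival motor neuron protein; the allele of the SMA mice is not given in the sources used here, and neither is the way in which the cells or tissue were collected. Per the labels' protocols, total RNA was prepared with a kit for very small samples and the cDNA was amplified with a system made for picogram amounts before labelling. Groups and replicate numbers were taken from the sample titles.

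Per the file headers, the first deposited table gives a signal intensity and a detection p-value for each probe and array. The submitters' processing notes name GenomeStudio, with no version. Between 23.9 and 38.5% of the signals of an array lay below 0, so a background had been subtracted before the intensity values were deposited. The detection p-values that the authors deposited come in steps of 1 in 936. The authors also deposited a table of normalized values on a log2 scale, by a method not given in the sources used here. Its values had a rank correlation of 1 with the signals of the same array, and the medians of its columns lay between 7.54 and 7.57. Its direction and scale could therefore be read from the values, while the method behind its centring stays unknown, and it served as an alternative. No column of values was left unused.

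The table held 45281 probes. The platform annotation gave 34885 of them 1 gene symbol, 18 several and 10378 none, for 19057 symbols in all. Of the named probes, 34807 had a gene number found in a gene table of the mouse assembly GRCm38.p6, which was used for names only and changed 0 symbols. Probes with several symbols were not named, and 3792 detected probes without a symbol were left out of the tests.

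Signals were background-corrected and normalized with limma 3.58.1 in R 4.3.3, by normexp convolution with control statistics inferred from the detection p-values, an offset of 16, quantile normalization over the 24 arrays and a log2 scale. Each gene was represented by the probe with the highest mean over all arrays; 9172 genes had more than 1 probe, and for SMA against WT the text says where another probe, above background on at least 3 arrays, pointed the other way for the largest changes that passed and for Cdkn1a, Mdm2, Ccng1 and Chat. Other probes of the further genes named were not compared. A gene was tested where its detection p was under 0.05 on all 3 arrays of at least 1 of the groups compared, and 11199 genes were detected in this sense in at least 1 group. A linear model with 1 mean per group was fitted to all 24 arrays, which left 16 residual degrees of freedom. Contrasts were tested with limma's moderated statistics with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were SMA against WT in each of the 4 tissues, the mean of these 4 differences, the difference between MMC and LMC, an F test of any difference among the 4 tissues, and LMC against MMC in WT mice. Adjusted p-values in the text are from limma and are two-sided; SE is the standard error of a log2 difference and SD the spread over the 3 arrays of a group.

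Lists of genes and of cell type markers were tested with limma's camera with a preset correlation of 0.01 between genes, where at least 5 members were tested, and adjusted over the lists of a comparison. The same test was repeated with a correlation estimated from the residuals, and its adjusted p is named as such. For the members of a list the count of genes past the threshold is given over all genes and adjusted over the list alone. The correlation of the log2 differences of any 2 tissues was compared with 100 random relabellings of genotype within tissues. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

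Named genes follow this rule. In each SMA against WT comparison they are the 10 largest rises and the 10 largest falls, by fitted difference, among genes past the threshold whose 3 SMA values lay on 1 side of the 3 WT values. Where fewer than 20 genes passed, they are the genes that passed and then, in each direction, the 5 of smallest unadjusted p without overlap, named as not passing. For the mean over tissues and LMC against MMC the rule took up to 10 passing genes in each direction, for MMC against LMC 5 in each direction, and for the F test up to 10 by p. Of each list described, it took the members that passed or those of smallest p. Smn1, Cdkn1a, Mdm2, Ccng1 and Chat were fixed for every comparison and markers of the local neurons for DRG and raphe; those not matched to a probe or not detected were not analysed here. Probes without a symbol, predicted loci and sex-linked genes were counted but not named.

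The steps were tested on simulated data with 200 genes changed by known amounts at the spread of the real arrays. At a true log2 difference of 1 and 2 respectively, 32 and 73 of 100 changed genes were recovered for SMA against WT in MMC (8770 genes), 18 and 67 in LMC (9080 genes), 31 and 67 in DRG (9927 genes) and 23 and 71 in the raphe (9424 genes). Of the calls, 3.67% in MMC, 0% in LMC, 4.85% in DRG and 5.05% in the raphe were false. The simulated noise was independent between genes and had the same spread in all groups, as the test assumes. These shares check the steps and do not measure the rate of false calls on the real arrays. With 3 arrays per group, their number limits the precision.

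The share of probes with a detection p under 0.05 ranged from 33.7 to 49.7% of an array. The correlation of an array with the others of its tissue, given as the median, was 0.859 for WT MMC replicate 3, 0.851 for SMA LMC replicate 2 and 0.935 for WT DRG replicate 1, the lowest of their tissues; in the raphe it ranged from 0.935 to 0.946. The highest correlation between any 2 arrays was 0.9971, and none was counted as a repeat of another. Each tissue lay on 1 chip of its own, and on each chip the WT arrays took the first 3 positions and the SMA arrays the last 3. Chip and tissue can therefore not be told apart, nor can position on the chip and genotype. Alternatives changed 1 choice at a time: the values used, background correction, normalization, filter, choice of probe, moderation, array weights, sex as a covariate, threshold, arrays in the fit, a replicate block and leaving out each array. List tests were rerun for only part of these, as named with the results on processing. A fit without the 3 arrays named above, and a test of a list without Smn1, were added after seeing the data.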

Results

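The arrays compared gene expression between SMA and WT mice at postnatal day 4 in the medial and lateral motor columns of the spinal cord, the DRG, which holds the cell bodies of sensory neurons, and the raphe, which holds serotonergic neurons. The medial column supplies the muscles along the trunk axis and the lateral column those of the limbs. The series thus allows the effect of genotype to be compared between samples of these columns. The samples are not shown to hold motor neurons alone. The oligodendrocyte gene Mbp stood at 11.3 in WT MMC and 8.44 in WT LMC, and the astrocyte gene Gfap at 10.8 and 7.37. Each of the 8 groups had 3 arrays. By tissue, between 38.2 and 44% of the probes of an array were above background in MMC, 33.7 and 42.9% in LMC, 43.8 and 49.7% in DRG and 43.6 and 47.7% in the raphe.

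Smn1, the gene whose loss underlies SMA, was above background on all 12 WT arrays and on 0 of the 12 SMA arrays. Its mean log2 level was 10.1 ± 0.652 (SD, n = 3) in WT MMC, 9.89 ± 0.465 in WT LMC, 9.74 ± 0.298 in WT DRG and 9.91 ± 0.196 in the WT raphe. In SMA mice it was 4.51 ± 0.075, 4.78 ± 0.238, 4.49 ± 0.0572 and 4.58 ± 0.132 in the same order. It was at least 26.8-fold lower in MMC (adjusted p = 5.04e-10), at least 21.7-fold lower in LMC (adjusted p = 3e-09), at least 26-fold lower in DRG (adjusted p = 1.94e-09) and at least 27.8-fold lower in the raphe (adjusted p = 1.33e-09). These bounds, like each "at least" below, set the mean of the brighter group against a floor. For each array of the dimmer group the floor is the lowest level of a probe above background on it, or the level of the gene itself where that is higher. The gene had 1 probe, and its position in the transcript was not analysed here. The bounds hold on the background-corrected scale used here. With the deposited normalized values the difference of Smn1 was -2.35 in MMC, -2.13 in LMC, -2.12 in DRG and -2.20 in the raphe. The genotype labels of all 24 arrays thus matched the level of Smn1. Whether its fall differs among tissues cannot be read from arrays on which it is below background.

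**Figure D1:**
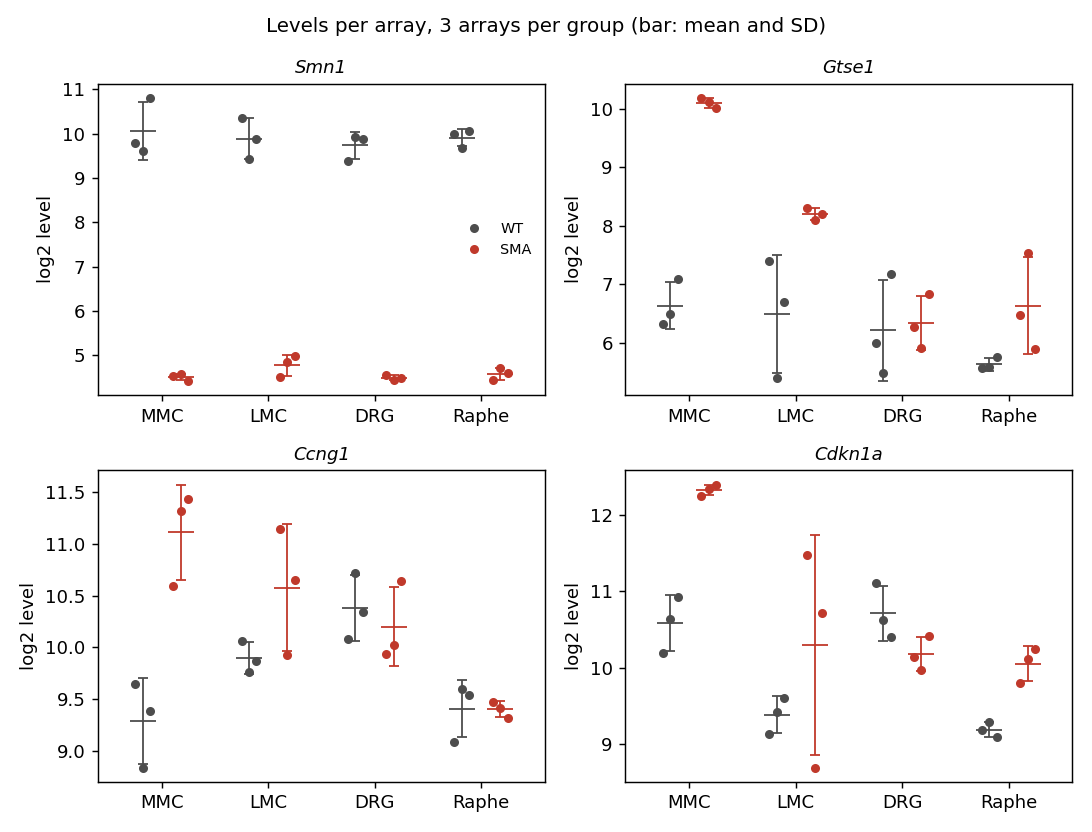
Normalized log2 level of Smn1, Gtse1, Ccng1 and Cdkn1a on each array (points) in WT and SMA mice in the 4 tissues, with the mean and SD of each group of 3 arrays. The group means of Smn1 lie between 4.49 and 4.78 in SMA and between 9.74 and 10.1 in WT, while Gtse1 reaches 10.1 in SMA MMC against 6.63 in WT MMC.

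Targets of p53 rose as a group in the SMA medial motor column. Of 27 measured targets, 24 lay above 0, with a median log2 difference of 0.83 and a mean of 0.96 (camera adjusted p = 3.4e-12; adjusted p = 0.00106 with an estimated correlation). The largest fitted rise among them was in Gtse1, a regulator of p53 and of microtubules, at 3.47 (SE 0.489, adjusted p = 0.000505), from 6.63 ± 0.402 in WT to 10.1 ± 0.0845 in SMA (SD, n = 3). Cdkn1a, the cell cycle inhibitor p21, rose by 1.74 (SE 0.402, adjusted p = 0.031) and Ccng1, which encodes cyclin G1, by 1.83 (SE 0.29, adjusted p = 0.00188). Perp, a membrane protein induced by p53 in apoptosis, rose by 2.38 (SE 0.455, adjusted p = 0.0125) and the kinase gene Plk2 by 1.43 (SE 0.338, adjusted p = 0.0341). Dcxr, a carbonyl reductase gene, was at least 2.89-fold higher (adjusted p = 0.00159). These 6 genes passed over all genes and 10 did when adjusted over the list alone. The other 4 were Mdm2, the ubiquitin ligase that restrains p53, at 0.86 (adjusted p = 0.0604 over all genes), Zfp365 at 0.83, Sesn1 at 1.18 and Rps27l at 1.41. In the genes of the intrinsic apoptosis machinery, by contrast, 10 of 14 lay below 0 (median -0.25, adjusted p = 0.642) and none passed; the difference between these lists was not tested.

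Over all 8770 genes tested in MMC, 114 passed, 59 higher and 55 lower in SMA. MMC arrays correlated less closely (0.859 to 0.911) than those of DRG (0.935 to 0.974) and the raphe (0.935 to 0.946). The spread was shared over all groups, so the count in MMC may be too high. Far fewer genes passed with only the MMC arrays in the fit, as given below. The count is thus no measure of the effect in MMC against other tissues. The smallest difference that passed was 0.49 on the log2 scale, 257 genes passed at 0.10, and 1285 genes (14.7%) had groups that did not overlap, where chance gives 10%. The naming rule took only passing genes with all SMA arrays on one side of all WT arrays, and Crip2, named from other comparisons, met this too. Padi1, a peptidylarginine deiminase, rose by 4.13 (SE 0.442, adjusted p = 1.36e-05; 9.99 ± 0.349 against 5.86 ± 0.906), and 2900060B14Rik was at least 8.79-fold higher (adjusted p = 0.0265). Fam183b rose by 3.76 (SE 0.738, adjusted p = 0.013), Coa4, a factor for cytochrome c oxidase assembly, by 2.76 (SE 0.562, adjusted p = 0.0156) and Plek2, of the pleckstrin family, by 2.53 (SE 0.483, adjusted p = 0.0125). Tcea3, a transcription elongation factor, was at least 5.48-fold higher (adjusted p = 5.6e-05) and Gbp5, a guanylate-binding protein induced by interferon, at least 3.39-fold (adjusted p = 0.0125). Tuft1 rose by 2.51 (SE 0.628, adjusted p = 0.046), Stard5, a carrier of cholesterol, by 2.47 (SE 0.548, adjusted p = 0.0258) and Crip2, a protein with LIM domains, by 1.83 (SE 0.241, adjusted p = 0.000201). In WT, 2 of 3 arrays detected Padi1 and Tuft1, and 1 of 3 detected Fam183b, Coa4 and Plek2.

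Among the genes that fell in MMC besides Smn1, Ranbp3l, of the Ran-binding protein family, was at least 10.3-fold lower (adjusted p = 0.000871). Polr1a, the largest subunit of RNA polymerase I, was at least 5.01-fold lower (adjusted p = 0.00114), the hyaluronan receptor gene Layn at least 4.16-fold (adjusted p = 0.0202) and the collagen gene Col8a1 at least 3.92-fold (adjusted p = 0.0231). Bbox1, the last enzyme of carnitine synthesis, fell by 2.82 (SE 0.695, adjusted p = 0.0432), Rnf122 fell by 2.69 (SE 0.556, adjusted p = 0.0179) and Yipf6, a protein of the Golgi, fell by 2.56 (SE 0.452, adjusted p = 0.00711). Sipa1l1, a regulator of Rap at synapses, fell by 2.53 (SE 0.478, adjusted p = 0.0125) and Dbpht2 fell by 2.43 (SE 0.573, adjusted p = 0.0341). Of the SMA arrays, 1 of 3 detected Bbox1 and Rnf122 and 2 of 3 detected Sipa1l1 and Dbpht2. Bbox1 and Tuft1 did not pass in 13 of 20 alternatives each. Another probe of the same gene pointed the other way for Tcea3 (-0.09), Col8a1 (0.23), Yipf6 (1 of its 3 other probes) and Polr1a (1 of 3). The other probes ranged from -1.35 to 0.105 for Yipf6 and from -0.352 to 0.655 for Polr1a, and that of Ranbp3l stood at -0.737. Polr1a and Yipf6 did not pass with the mean of all detected probes. All other probes of Gtse1, Cdkn1a and Ccng1 lay above 0, at 0.96 to 2.65.

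Markers of motor neurons as a group did not pass in MMC (median -0.01, mean -0.23, 16 tested, adjusted p = 0.461), and Chat, the enzyme that makes acetylcholine, differed by 0.04 (SE 0.452, adjusted p = 0.979). A pair of them passed. Mmp9, a metalloproteinase of fast motor neurons, fell by 2.16 (SE 0.416, adjusted p = 0.0125; 2 of 3 SMA arrays above background). Chodl, a membrane protein of fast motor neurons, fell by 1.34 (SE 0.295, adjusted p = 0.024). Neurofilaments, microtubules and axonal transport had 12 of 18 members below 0 (median -0.19, mean -0.34, adjusted p = 0.0338; adjusted p = 0.499 with an estimated correlation). Of these Map1a, a microtubule-associated protein of neurons, fell by 1.92 (SE 0.407, adjusted p = 0.0202), while Nefl (-0.58) and Nefm (-0.58) did not pass. Replication-dependent histones had 16 of 18 members above 0 (median 0.70, mean 0.69, adjusted p = 0.0052; adjusted p = 0.891 with an estimated correlation). Of them 0 passed over all genes and 2 adjusted over the list alone, H1f2 at 1.38 and H2ac7 at 0.92. Histone genes are near copies of each other, so their probes may not tell them apart. Elsewhere, the immediate early gene Fos rose by 2.15 (SE 0.461, adjusted p = 0.0207), but its list of 6 tested members had a median of -0.62 and did not pass. The calcium channel gene Cacna1c was at least 1.89-fold higher (adjusted p = 0.0266) and the synaptic vesicle gene Syt2 at least 1.34-fold lower (adjusted p = 0.0416). Among genes linked to SMA in earlier work, Chodl fell, and Mdm2, Stmn1 at 0.48 and Mdm4 at 1.91 passed upward when adjusted over the list alone; the list did not pass (adjusted p = 0.991).

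Of the 30 lists tested in MMC, 3 passed, the p53 targets, the histones and the neurofilament list, and 1, the p53 targets, held with an estimated correlation. Markers of other cells in MMC stood at medians of -0.11 for oligodendrocytes (adjusted p = 0.642), 0.13 for astrocytes (adjusted p = 0.969), 0.33 for microglia and macrophages (adjusted p = 0.965) and -0.16 for endothelial cells and pericytes (adjusted p = 0.644). The list of the SMN complex had a median of 0.14 but a mean of -0.08 and a test in the lower direction (adjusted p = 0.461); Smn1 was the only member that passed. The count of 114 genes was 277 without WT MMC replicate 2, 182 without SMA MMC replicate 2 and 351 without the array of lowest correlation in each of MMC, LMC and DRG, and 5 with only the 6 MMC arrays in the fit. Cdkn1a did not pass without WT MMC replicate 1 or any SMA MMC replicate; its adjusted p ranged from 7.47e-05 to 0.0899 over the alternatives, and its difference from 1.54 to 1.99.

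**Figure D2:**
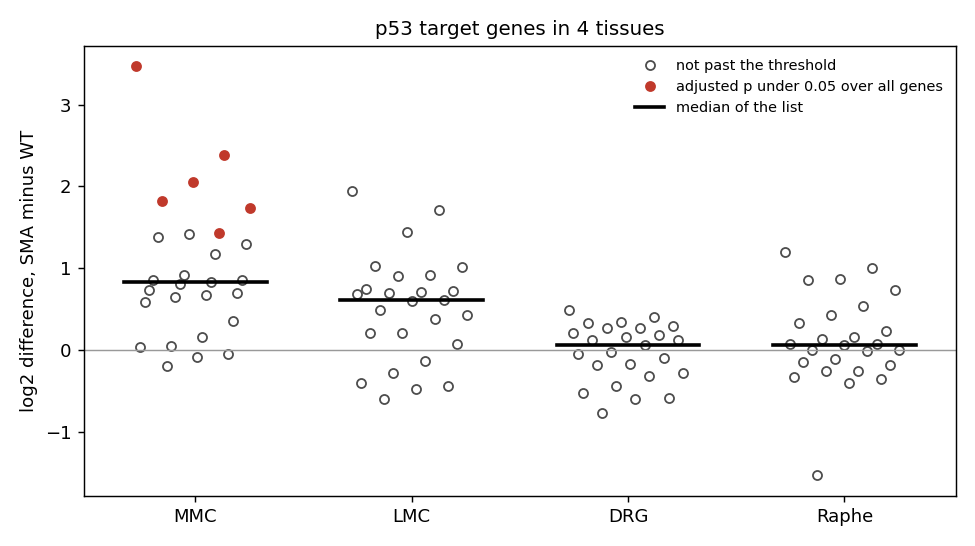
Log2 difference, SMA minus WT, of each measured p53 target (points) in the 4 tissues; filled points have an adjusted p under 0.05 and the line marks the median. The medians are 0.83 in MMC, 0.60 in LMC, 0.06 in DRG and 0.06 in the raphe; under median scaling that of DRG turns to -0.19.

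In the lateral motor column the p53 targets also stood higher as a group, with 20 of 26 above 0, a median of 0.60 and a mean of 0.51 (adjusted p = 8.82e-06; adjusted p = 0.0206 with an estimated correlation). The median of these targets ranged from 0.234, with the deposited normalized values, to 0.7 over the alternatives. None of them passed over all genes. Adjusted over the list alone 4 did, Polk, a polymerase that copies damaged DNA, at 1.95, Gtse1 at 1.71, Zfp365 at 0.74 and Mdm2 at 0.69. Another probe of Mdm2 pointed the other way (-0.38), as did another of Cdkn1a (-0.01). Of all 9080 genes tested, 2 passed, Smn1 and Crip2. Crip2, a gene that also passed in MMC, rose by 1.67 (SE 0.241, adjusted p = 0.00229), from 6.59 ± 0.359 in WT to 8.27 ± 0.427 in SMA (SD, n = 3). Cdkn1a differed by 0.91 (SE 0.402, adjusted p = 0.709) with an SD of 1.43 among the SMA arrays, Ccng1 by 0.68 (adjusted p = 0.709) and Chat by -0.04 (adjusted p = 0.99). At an unadjusted p under 0.05 limma counted 623 genes, and 939 genes (10.3%) had groups that did not overlap, against 10% by chance.

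Among the genes of smallest p in LMC that did not pass, Fbp2, a fructose bisphosphatase of muscle, was at least 6.19-fold higher (adjusted p = 0.0518) and the tubulin gene Tubb6 stood at 2.37 (adjusted p = 0.106). The others above 0 were Zcchc2 at least 3.73-fold, 4921507P07Rik at least 2.5-fold, and Polk (adjusted p = 0.106 each). Below 0 they were the transcription factor gene Cux1 at -1.97 (adjusted p = 0.193), Trpm6, a magnesium channel, at least 3.68-fold lower (adjusted p = 0.209), and Zhx3 at -1.30 (adjusted p = 0.209). Next came 4930415L06Rik, at least 1.39-fold lower (adjusted p = 0.238), and Ppic at -1.88 (adjusted p = 0.415). Among the WT arrays, 2 of 3 detected Tubb6 and 1 of 3 detected Polk.

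Of the 30 lists in LMC, 9 passed and 1 held with an estimated correlation, the p53 targets. The SMN complex and snRNP assembly genes lay lower, 18 of 23 below 0 (median -0.36, mean -0.60, adjusted p = 8.82e-06; adjusted p = 0.234 with an estimated correlation). Without Smn1 in the list the median was -0.35 and the adjusted p 0.0319, within a range of 1.77e-06 to 0.234 over the alternatives. Ribosomal proteins (15 of 20 below 0, median -0.26, mean -0.54, adjusted p = 0.00155), histones (16 of 19, median -0.36, adjusted p = 0.0185) and cholesterol synthesis (11 of 15, median -0.29, adjusted p = 0.0185) also stood lower. These 3 had adjusted p = 0.477, 0.574 and 0.482 with an estimated correlation. The same held for the neurofilament list (14 of 18 below 0, median -0.24, adjusted p = 0.0185; adjusted p = 0.291 with an estimated correlation), in which Map1b at -0.32 passed when adjusted over the list alone. Oxidative phosphorylation stood lower as well (21 of 34, median -0.10, adjusted p = 0.0257; adjusted p = 0.574 with an estimated correlation). Microglia and macrophage markers stood higher (4 of 5 above 0, median 0.89, adjusted p = 0.0185; adjusted p = 0.291 with an estimated correlation). So did immediate early genes (median 0.26, 6 of 9 above 0, adjusted p = 0.0421; adjusted p = 0.477 with an estimated correlation). Fos at 1.47 and Fosb, at least 1.21-fold higher, passed when adjusted over the list alone. SMA LMC replicate 2 stood apart from the other arrays, with 33.7% of probes above background; on it the histones lay -1.04, cholesterol synthesis -0.78, ribosomal proteins -0.65 and the SMN list -0.58 from the mean of the other two SMA LMC arrays. Without it the medians of the SMN list, the histones and the ribosomal proteins were 0.01, 0.02 and 0.04, and 3 genes passed. Without it the lists of histones, ribosomal proteins, oxidative phosphorylation, neurofilaments, cholesterol synthesis and immediate early genes did not pass. The microglia list did not pass without WT LMC replicate 3, with a median of 0.39, or SMA LMC replicate 1. Over all genes, 25 passed without SMA LMC replicate 3 and 4 without SMA LMC replicate 1.

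In the DRG, Smn1 was the only gene of 9927 that passed. At an unadjusted p under 0.05 limma counted 142 genes (1.43%), a smaller share than chance gives at that threshold. The spread was shared over the 8 groups, so the test may be too strict in DRG. The lack of calls there does not show that genotype had no effect. There were 858 genes (8.64%) without overlap of the groups, against 10% by chance. None of the fixed genes passed: Cdkn1a differed by -0.53 (SE 0.402), Mdm2 by 0.11, Ccng1 by -0.18, Chat by 0.17, Pvalb, a marker of proprioceptive neurons, by -0.40 and Scn10a, a sodium channel of nociceptors, by 0.22. Another probe of Mdm2 (-0.64) and of Chat (-0.03) pointed the other way. With array weights 43 genes passed in DRG, for a reason that was not tested. Above 0, the genes of smallest p were Glra2, a glycine receptor subunit, at 1.52 (adjusted p = 0.255; 1 of 3 WT arrays above background), and 4930578I06Rik, at least 1.6-fold (adjusted p = 0.884). They were followed by the dopamine receptor gene Drd1 at 0.83, the myelin gene Pmp2 at 1.23 and Prss48 at 1.57. Below 0 they were Maats1 at -0.79, Arhgef4 at -1.27, Ms4a3 at -0.88, Cldn34c1 at least 1.41-fold lower and Acsl4, which activates arachidonic acid, at -0.72; none of these passed.

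Of the 30 lists tested in DRG, 0 passed. The nearest was the SMN list, with a median of -0.13 (adjusted p = 0.0534). This list holds Smn1 itself and was not tested without it in DRG, so no fall of its other members is shown. Sensory neuron markers had a median of -0.08 with 11 of 15 below 0 (adjusted p = 0.929). Schwann cell and satellite glia markers had a median of 0.20 (adjusted p = 0.148), with Pmp2 past the threshold when adjusted over the list alone. The p53 targets had a median of 0.06 and a mean of -0.04 (adjusted p = 0.929). Among Hox genes, Hoxa11 at 1.12 passed when adjusted over the list alone. Median scaling moved the median of all genes in DRG from -0.03 to -0.23, and that of the p53 targets to -0.19, so small shifts of either direction are not settled here.

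In the raphe, the neuropeptide genes Npy and Crh and the Hox genes Hoxa5 and Hoxc5 were lower in SMA. Npy, neuropeptide Y, fell by 2.52 (SE 0.316, adjusted p = 0.000246), from 7.58 ± 0.803 to 5.06 ± 0.498 (SD, n = 3; 1 of 3 SMA arrays above background), and Crh, corticotropin-releasing hormone, was at least 3.02-fold lower (adjusted p = 0.0082). Of the Hox genes, which set position along the axis, Hoxa5 fell by 2.94 (SE 0.556, adjusted p = 0.0165; 2 of 3 SMA arrays) and Hoxc5 was at least 2.32-fold lower (adjusted p = 0.0165). Of 9424 genes tested, 23 passed, 9 higher and 14 lower; 41 passed at 0.10, and 1370 genes (14.5%) had no overlap of groups, against 10% by chance.

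Among the rises in the raphe, C1ql2, a secreted protein of synapses, was at least 4.19-fold higher (adjusted p = 0.00228). Gad1, which makes the transmitter GABA, rose by 2.10 (SE 0.441, adjusted p = 0.0382; 9.96 ± 0.841 against 7.86 ± 0.234). Dio3, the deiodinase that inactivates thyroid hormone, rose by 1.26 (SE 0.238, adjusted p = 0.0165), Cyp39a1, an oxysterol hydroxylase, by 1.18 (SE 0.21, adjusted p = 0.00964) and the potassium channel gene Kcnc4 by 1.04 (SE 0.204, adjusted p = 0.0232). Acrbp rose by 1.77 (SE 0.363, adjusted p = 0.0354) and Rassf4 by 1.42 (SE 0.3, adjusted p = 0.0385). Socs7, of the suppressors of cytokine signalling, was at least 2.04-fold higher (adjusted p = 0.00964) and 4930412O13Rik at least 1.57-fold (adjusted p = 0.0381). The growth factor gene Igf1 fell by 3.38 (SE 0.571, adjusted p = 0.0082), Mctp1 fell by 2.65 (SE 0.457, adjusted p = 0.0082) and the matrix gene Tnc fell by 2.53 (SE 0.528, adjusted p = 0.0381). The cadherin gene Cdh8 fell by 2.43 (SE 0.417, adjusted p = 0.0082) and the phosphodiesterase gene Pde1a fell by 2.19 (SE 0.337, adjusted p = 0.00323). The SD of Igf1 was 1.93 among SMA arrays and 0.51 among WT arrays. In WT, 1 of 3 arrays detected Acrbp and 2 of 3 Rassf4 and Dio3; in SMA, 1 of 3 detected Mctp1. The other probe of Acrbp (-0.18) and of Cyp39a1 (-0.12) pointed the other way.

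**Figure D3:**
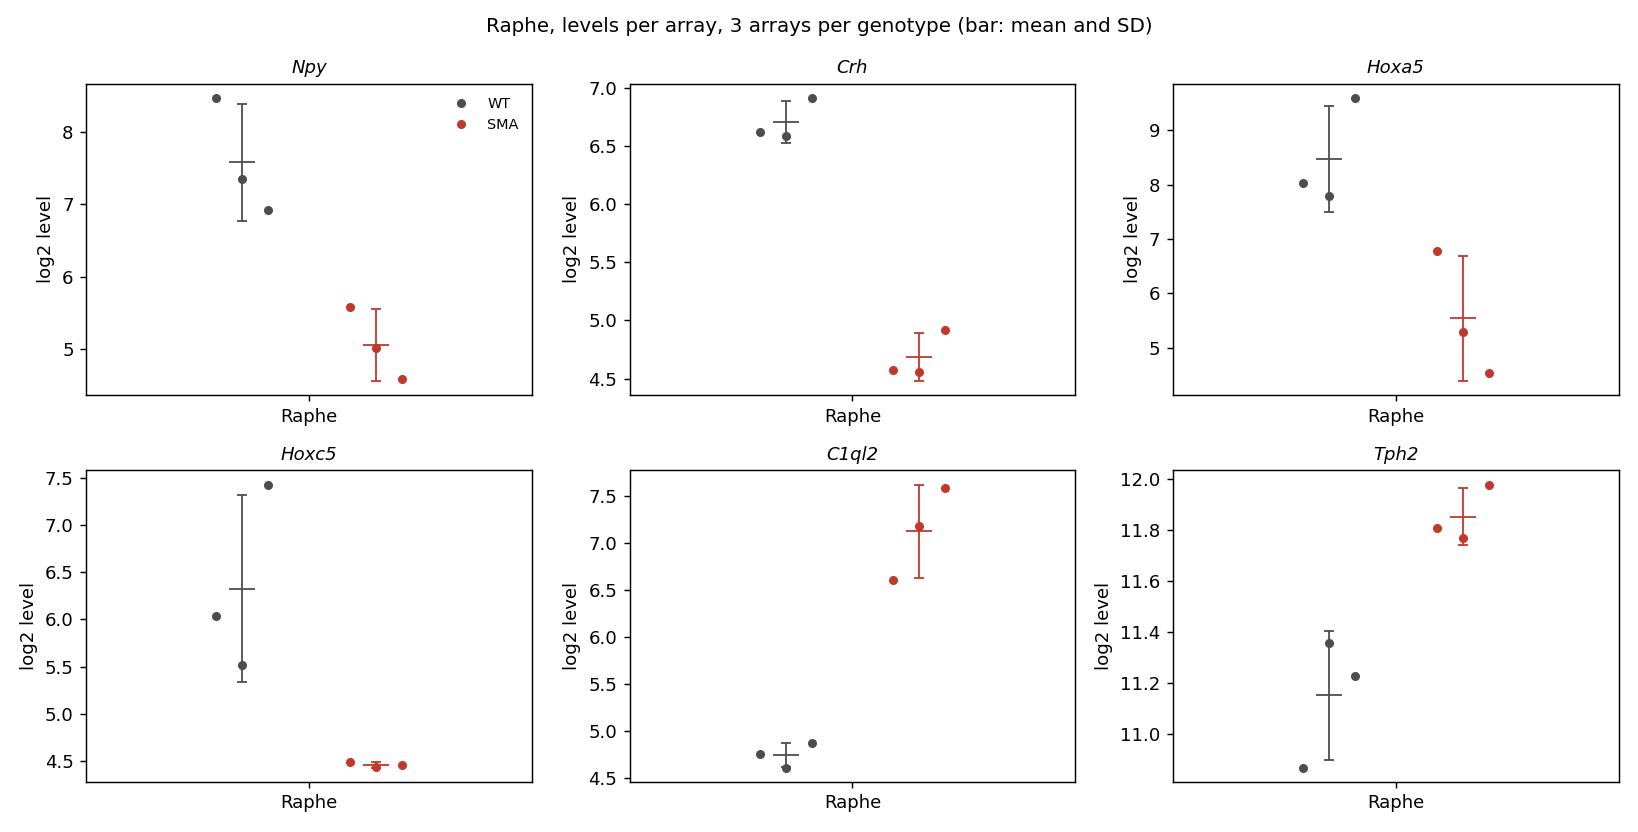
Normalized log2 level of Npy, Crh, Hoxa5, Hoxc5, C1ql2 and Tph2 on each raphe array (points) in WT and SMA mice, with the mean and SD of each group of 3 arrays. The SMA arrays lie below the WT arrays for the first 4 genes and above them for C1ql2, while Tph2 did not pass (11.9 against 11.2).

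Serotonergic neuron markers stood higher in the SMA raphe as a group, 7 of 8 above 0 (median 0.63, mean 0.63, adjusted p = 0.00557; adjusted p = 0.0764 with an estimated correlation). None passed over all genes. Tph2, which makes serotonin, differed by 0.70 (SE 0.389, adjusted p = 0.806) and its transporter Slc6a4 by 0.67 (SE 0.356, adjusted p = 0.786). Gch1, which makes the cofactor of serotonin synthesis, passed at 1.25 when adjusted over the list alone. Hox genes had 7 of 11 members below 0 (median -0.26, mean -0.69, adjusted p = 0.00557; adjusted p = 0.386 with an estimated correlation), with 2 past the threshold and 3 when adjusted over the list alone, the third being Hoxb5 at -1.73. Hoxb4 stood at -1.03, Hoxa2 at 0.29, Hoxa3 at 0.23, Hoxa4 at 0.12 and Hoxd3 at 0.33, none of which passed. Without SMA replicate 3 neither list passed, nor the serotonergic list without WT replicate 1 or the Hox list without SMA replicate 2; over the alternatives their adjusted p ranged from 8.96e-13 to 0.0921 and from 2.54e-06 to 0.386. Beside these, En1, a gene of the rostral hindbrain and midbrain, was 2.47 higher in SMA (SE 0.917, adjusted p = 0.461) and spread from 5.72 to 10.5 among the SMA arrays. Histones had 18 of 20 above 0 (median 0.26, adjusted p = 0.011; adjusted p = 0.564 with an estimated correlation), with 0 past the threshold and H1f2 at 1.37 adjusted over the list alone. The histone list did not pass without SMA replicate 2 (median -0.0247) or WT replicate 2 (0.144). Axon injury genes had 8 of 12 below 0 (median -0.27, adjusted p = 0.011; adjusted p = 0.206 with an estimated correlation), with Npy past the threshold and Jun at -0.75. The axon injury list did not pass without SMA replicate 1 or 3.

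Inhibitory interneuron markers did not pass as a list in the raphe (median 0.76, adjusted p = 0.28), with Gad1 up, Npy down and Gad2 at 1.38 past the threshold when adjusted over the list alone. Markers of other cells stood at medians of -0.19 for astrocytes (adjusted p = 0.449), -0.19 for oligodendrocytes (adjusted p = 0.52), 0.19 for microglia and macrophages (adjusted p = 0.703) and -0.28 for endothelial cells (adjusted p = 0.193). The p53 targets had a median of 0.06 (adjusted p = 0.449). Of them Polk, which stood at 1.95 in LMC, stood at -1.54 in the raphe and passed when adjusted over the list alone, but not over all genes (adjusted p = 0.167). Cdkn1a differed by 0.86 (adjusted p = 0.7), Mdm2 by 0.13 and Ccng1 by -0.01, which turns to 0.01 under median scaling. Another probe of Cdkn1a (-0.38) and of Mdm2 (-0.12) and the other probes of Ccng1 (0.11 and 0.48) pointed the other way. Of 32 lists 4 passed and 0 held with an estimated correlation. The count of 23 genes was 7 without WT replicate 3, 11 without SMA replicate 3, 37 without SMA replicate 1 and 46 without the array of lowest correlation in each of MMC, LMC and DRG. Gad1, Tnc and Rassf4 did not pass in 13 of 21, 13 of 21 and 12 of 20 alternatives.

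Averaged over the 4 tissues, 6 of 11199 genes passed, 4 higher and 2 lower in SMA. Besides Smn1, these were Gtse1 at 1.58 (SE 0.244, adjusted p = 0.00572), C1ql2 at 1.11 (SE 0.175, adjusted p = 0.00574), Tcea3 at 1.09 (SE 0.186, adjusted p = 0.0112) and Crip2 at 0.94 (SE 0.121, adjusted p = 0.000402). Nefl, the light neurofilament chain, was lower, at -0.59 (SE 0.0985, adjusted p = 0.0109). Nefl stood at -0.58 in MMC, -0.40 in LMC, -0.51 in DRG and -0.85 in the raphe, and passed in none of them alone. Gtse1 stood at 3.47, 1.71, 0.12 and 1.00 in the same order, and C1ql2 at 1.08 in MMC and 0.81 in LMC, was below background in DRG, and rose in the raphe from background in WT. Tcea3 was below background in LMC and DRG, so that the averages of C1ql2 and Tcea3 are fitted values and not measured sizes. Cdkn1a averaged 0.74 (SE 0.201, adjusted p = 0.324), Mdm2 0.45 (adjusted p = 0.26), Ccng1 0.58 (adjusted p = 0.26) and Chat 0.10, with another probe of Chat below 0.

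The p53 targets averaged higher, with 27 of 31 above 0, a median of 0.32 and a mean of 0.36 (adjusted p = 1.93e-13; adjusted p = 0.0003 with an estimated correlation). Of them 1 passed over all genes and 8 when adjusted over the list alone, among them Perp at 1.01 and Plk2 at 0.70. Whether the shift of this list differs between MMC and DRG or the raphe was not tested. The neurofilament list averaged lower, with 14 of 18 below 0 (median -0.12, adjusted p = 5.44e-05; adjusted p = 0.0503 with an estimated correlation). It had 1 member past the threshold over all genes and 3 adjusted over the list alone, Nefl, Nefm at -0.51 and Map1b at -0.22. Map1b is also in the list of chromosome 13 neighbours of Smn1, which did not pass. Adjusted over that list alone Map1b passed (adjusted p = 0.00168), and whether its position bears on its fall was not tested. The SMN list (median -0.08, adjusted p = 6.67e-07; adjusted p = 0.542 with an estimated correlation) did not pass without Smn1 (adjusted p = 0.777, within 5.78e-08 to 0.777 over the alternatives). Oxidative phosphorylation (median -0.05, adjusted p = 0.0242), endothelial markers (median -0.37, adjusted p = 0.0429) and mitotic genes (median 0.13, 12 of 14 above 0, adjusted p = 0.0345) had adjusted p = 0.542, 0.47 and 0.47 with an estimated correlation.

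The direct test of whether genotype acted differently in MMC and LMC passed for 2 of 9697 genes. Ranbp3l had a difference of -5.20 (SE 0.828, adjusted p = 0.0218): it was below background in SMA MMC and stood at 1.23 in LMC (adjusted p = 0.709). Dennd3, a regulator of vesicle traffic, had 2.11 (SE 0.363, adjusted p = 0.0324): it was above background on the 3 SMA arrays of MMC, at 6.79 ± 0.698, and on no WT MMC or LMC array. With arrays at background on one side, neither value is a measured size. The differences between columns were not significant for Cdkn1a at 0.83 (SE 0.569, adjusted p = 0.648), Ccng1 at 1.14 (SE 0.41, adjusted p = 0.41), Mdm2 at 0.17 (adjusted p = 0.902) or Chat at 0.08, and Smn1 could not be compared, being at background in SMA. Nor were the p53 targets shown to differ (median 0.28, 21 of 30 above 0, adjusted p = 0.0592; adjusted p = 0.601 with an estimated correlation). The larger number of p53 targets past the threshold in MMC is thus not shown to be a difference between columns. Of 30 lists, 2 passed and 0 held with an estimated correlation. Those were histones (19 of 19 above 0, median 1.01, adjusted p = 1.25e-05) and ribosomal proteins (18 of 20, median 0.76, adjusted p = 4e-05), each with adjusted p = 0.601 with an estimated correlation. Mmp9 at -2.29 and Chodl at -1.35 passed when adjusted over the motor neuron list alone.

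The F test across the 4 tissues passed for 7 of 11199 genes: Padi1, Dennd3, Npy, Crip2, Polr1a, Ranbp3l and Tcea3. The other genes past the threshold in a single tissue did not pass this test and are not shown to differ between tissues. Padi1 rose in MMC and stood at -0.27 in DRG, Crip2 at -0.09 in DRG and 0.36 in the raphe, and Polr1a at 0.24 in LMC, 0.83 in DRG and 0.17 in the raphe. Over all genes, the differences in MMC and LMC correlated at 0.0696 across 8153 genes, below the highest value of 0.102 among other labellings (adjusted p = 0.91). The other 5 pairs of tissues ranged from -0.125 to 0.0762 (adjusted p = 0.91 each), and genes are not independent replicates. Of 86 genes past the threshold in MMC and tested in LMC, 57 (66.3%) had the same direction in LMC, with a median ratio of 0.137, and Crip2 and Smn1 passed in both. For DRG it was 35 of 89 (39.3%) and for the raphe 44 of 85 (51.8%). Over all genes the shares were 51.7%, 43.5% and 49.5% in the same order, and the difference from them was not tested.

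In WT mice some genes of lateral motor neurons were higher in the lateral column, and markers of oligodendrocytes were higher in the medial column. Aldh1a2, which makes retinoic acid in lateral motor neurons, was 3.79 higher in LMC (SE 0.489, adjusted p = 8.36e-05; 9.37 ± 0.516 against 5.59 ± 0.902, SD, n = 3). Isl1, a transcription factor of motor neurons, was 2.06 higher (SE 0.28, adjusted p = 0.000178). Oligodendrocyte markers were lower in LMC in 12 of 12 cases (median -1.48, adjusted p = 4.25e-15; adjusted p = 0.00605 with an estimated correlation). Of these 7 passed over all genes and 8 adjusted over the list alone. Mbp, myelin basic protein, stood at -2.88 (SE 0.31, adjusted p = 3.19e-05) and Mobp at -4.89 (SE 0.776, adjusted p = 0.000859). Mag stood at -3.15 (adjusted p = 0.00114) and Cldn11 at -2.59 (adjusted p = 0.00163). Of the 7, Enpp6 alone had groups that overlapped, at -2.04 (adjusted p = 0.02). Gfap, of astrocyte filaments, stood at -3.41 (SE 0.43, adjusted p = 8.36e-05; 7.37 against 10.8). Of 9186 genes, 313 passed, 171 higher and 142 lower in LMC, and 2419 (26.3%) did not overlap, against 10% by chance.

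**Figure D4:**
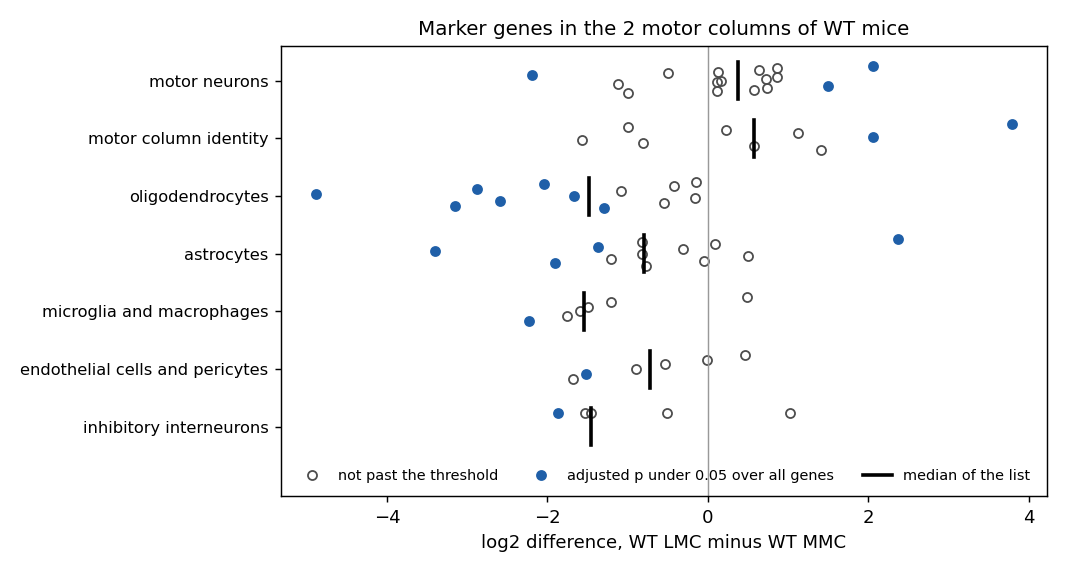
Log2 difference, WT LMC minus WT MMC, of the members of 7 marker lists (points, 1 per gene), with filled points for an adjusted p under 0.05 and a line at the median. All 12 oligodendrocyte markers lie below 0, with a median of -1.48, and motor column identity genes lie on both sides, with a median of 0.57.

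Other genes higher in WT LMC were Myom2, of the muscle sarcomere, at least 7.75-fold (adjusted p = 0.00276), the oxygen sensor Egln3 at 3.52 (adjusted p = 0.0011) and Lmo1 at 3.49 (adjusted p = 0.000912). Tmem132c was at least 6.43-fold higher (adjusted p = 0.000974), and Sostdc1, an antagonist of bone morphogenetic proteins, stood at 3.26 (adjusted p = 8.36e-05). Mgat4c stood at 3.07 (adjusted p = 0.000454), Polr3g, a subunit of RNA polymerase III, at 2.96 (adjusted p = 0.012), the axon guidance gene Efna5 at 2.89 (adjusted p = 0.00712) and Nxph2 at 2.87 (adjusted p = 0.00163). Lower in LMC were Ranbp3l at -3.65 (adjusted p = 0.000912), the myelin gene Mal at -3.61 (adjusted p = 0.0118) and Calb2, the calcium buffer calretinin, at -3.50 (adjusted p = 8.36e-05). Robo4 of endothelial cells stood at -3.27 (adjusted p = 0.00134), Pgm5 was at least 4.3-fold lower (adjusted p = 0.00237) and Zfp821 stood at -2.85 (adjusted p = 0.00279). In MMC, 2 of 3 arrays detected Aldh1a2, Egln3, Efna5 and Nxph2 and 1 of 3 Lmo1, Sostdc1, Mgat4c and Polr3g; in LMC, 2 of 3 detected Mobp and Mal and 1 of 3 Ranbp3l and Robo4.

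Motor column identity genes did not pass as a list (median 0.57, adjusted p = 0.113). Adjusted over the list alone, 4 were higher in LMC: Aldh1a2, Isl1, Foxp1 at 1.41 and Lhx1 at least 1.53-fold, the last 2 being genes of lateral neurons. On the same terms 3 were lower, Lhx3 at -0.81 and Mecom at -1.57, both genes of medial neurons, and Mnx1 at -1.0. Motor neuron markers had a median of 0.37 (adjusted p = 0.797). Isl1 and the neuropeptide gene Calcb at 1.49 (adjusted p = 0.0102) were higher and the peptide gene Uts2 at -2.19 (adjusted p = 0.000286) lower. Chat at 0.86 (adjusted p = 0.276) and Smn1 at -0.18 (adjusted p = 0.797) did not pass. Cdkn1a stood at -1.20 (adjusted p = 0.0952), Ccng1 at 0.60 (adjusted p = 0.23) and Mdm2 at -0.16.

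Markers of microglia also stood lower in LMC (median -1.54, adjusted p = 0.000202; adjusted p = 0.1 with an estimated correlation), in which C1qb was at least 3.27-fold lower (adjusted p = 0.0333). Astrocyte markers did too (median -0.80, adjusted p = 0.000279; adjusted p = 0.135 with an estimated correlation); of these Gfap, Aqp4 at -1.91 and Agt, at least 2.12-fold, were lower and S100b at 2.37 was higher. Complement and class I genes (8 of 8 below 0, median -0.63, adjusted p = 0.0016) and endothelial cells (median -0.72, adjusted p = 0.0153) had adjusted p = 0.152 each with an estimated correlation. Their medians were -0.57 and -0.55 with members below background set at their bound. No list median changed in this way in the SMA comparisons of single tissues. Inhibitory interneuron markers (median -1.45, adjusted p = 0.033; adjusted p = 0.367 with an estimated correlation) included Gad1 at -1.87 (adjusted p = 0.0194). Ion channels stood higher (median 0.55, adjusted p = 0.033; adjusted p = 0.135 with an estimated correlation), with the sodium channel subunit Scn4b at 2.55 (adjusted p = 0.000274). Cholesterol synthesis stood higher too (median 0.65, adjusted p = 0.0305; adjusted p = 0.608 with an estimated correlation), with Hsd17b7 at 0.87 (adjusted p = 0.0194). The columns lay on separate chips, so chip and column cannot be told apart. They also differed in markers of other cells, so a difference between columns need not be one between motor neurons. Median scaling, which moved the median of all genes from 0.15 to 0.33, passed 489 genes with 78.3% of them higher, against 54.6% higher in the 313. Without WT LMC replicate 1, 2 or 3 the count was 130, 161 or 149 and without WT MMC replicate 2 it was 507.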

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

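Of the tests below, those on WT MMC replicate 3, on glial RNA in MMC, on SMA LMC replicate 2 and on the share of serotonergic neurons were chosen after the result was seen; the relabellings and the test of En1 and En2 were planned. Results are listed here because the effect of genotype in one tissue differed from that in another by a test of the difference itself. By the F test across the 4 tissues these were Padi1 (F = 22.5, adjusted p = 0.0062), Dennd3 (F = 18.4, adjusted p = 0.0161), Npy (F = 15.8, adjusted p = 0.0257), Crip2 (F = 15.7, adjusted p = 0.0257), Polr1a (F = 15.4, adjusted p = 0.0257), Ranbp3l (F = 14.7, adjusted p = 0.0298) and Tcea3 (F = 13.9, adjusted p = 0.0372). Padi1 kept its call under all 37 alternatives. The call ended for Dennd3 in 3 of 37, Npy in 9 of 37, Crip2 in 9 of 38, Polr1a in 10 of 37, Ranbp3l in 18 of 37 and Tcea3 in 27 of 37. Padi1, Dennd3 and Tcea3 rose in all 3 SMA MMC arrays and Polr1a and Ranbp3l were lower in all 3, on the probe used. Other probes showed much smaller or opposite differences in MMC for Polr1a (-0.352 to 0.655), Ranbp3l (-0.737) and Tcea3 (-0.0928). Crip2 was higher in all 3 SMA arrays of MMC and of LMC, and Npy lower in all 3 of the raphe. With genotype relabelled at random within each tissue, 2 of 100 labellings, the real one included, gave as many as 7 genes. The highest of the others gave 9, more than the real one, so chance is not excluded for this count. Npy and Dennd3 were at or below background in the other 3 tissues, apart from 1 of 3 arrays in some groups, so for them the difference is also one of where the gene is measured at all.

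Between MMC and LMC the tested differences were Dennd3 at 2.11 and Ranbp3l at -5.2 on the log2 scale, and among the lists the replication-dependent histones with a median of 1.01 and the ribosomal proteins with 0.758. With an estimated correlation both lists had adjusted p = 0.601 and with fry 0.334, so neither call holds there; over their alternatives the adjusted p ranged from 2.12e-06 to 0.601 and from 7.32e-07 to 0.601. Within these columns Dennd3 was above background on the SMA MMC arrays alone, and Ranbp3l on no SMA MMC array and 1 of 3 WT LMC arrays, so their values are fitted and not measured sizes. For the count of 2 genes, 28 of 100 relabellings within the columns, the real one included, gave as many and the highest gave 29, so chance cannot be excluded. A labelling that gives many times the real count may point to a structure of the arrays other than genotype, which was not tested. Of the list medians, the histones fell to 0.772 and the ribosomal proteins to 0.329 without SMA LMC replicate 2.

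The first pattern weighed is the rise of the p53 targets in SMA MMC. The tables argue against WT MMC replicate 3, the MMC array least like its tissue, as its source, since the median of the list stayed at 0.777 without it. They argue against more oligodendrocyte RNA on the SMA arrays too, since oligodendrocyte markers, which separate the columns in WT, had a median of -0.108. Its SE of 0.132 is over markers, which share the same arrays. Markers of astrocytes (median 0.127) and of microglia and macrophages (0.332) stood above 0, so RNA of those cells stays open. Position on the chip follows genotype and stays open, as does whether the motor neurons themselves or other cells of the column hold the rise. A response of p53 to the loss of Smn1 is a candidate explanation that the design names but that was not tested separately from these.

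The second pattern is that few genes passed in LMC. Without SMA LMC replicate 2, 3 genes passed, against 25 without SMA LMC replicate 3 and 4 without SMA LMC replicate 1. Each of these fits leaves 2 SMA arrays and less power, so the low count does not settle whether this array is the reason. The spread shared over all groups may add to the gap from MMC. With only the arrays compared in the fit, far fewer genes passed in MMC. RNA of other cells on SMA LMC replicate 2 may add to its distance from the other arrays: glial markers lay 0.148 above the other two SMA LMC arrays in the median, too small to decide, and motor neuron markers lay higher as well (0.503, SE 0.376). A smaller effect of genotype in LMC than in MMC is a biological explanation that stays open, since the test of the difference found 2 genes.

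The third pattern is lower Hox genes, 7 of 11 below 0, with higher serotonergic markers in the SMA raphe; neither list passes with an estimated correlation (adjusted p = 0.386 and 0.0764) and no serotonergic marker passed over all genes. Samples taken from another level of the brainstem may explain both: En1 and En2 of the rostral hindbrain had a fitted mean of 1.49 (SE 0.815 over arrays), but En2 was above background on 0 of 3 WT and 1 of 3 SMA arrays and was not tested. En1 alone stood at 2.47 (SE 0.917, adjusted p = 0.461), so the test does not decide and this stays open. A larger share of serotonergic neurons in the SMA samples may explain the rise too and would lower other cell types alike, but while 4 of them had a joint median of -0.217 (SE 0.0494), erythroid cells had -1.9 (SE 0.885 over genes), fibroblasts and meninges -0.715 (SE 0.264), Schwann and satellite glia -0.401 (SE 0.116), motor neurons -0.393 (SE 0.218), microglia 0.194 (SE 0.156) and inhibitory interneurons 0.764 (SE 0.647), so this stays open. An effect of genotype on raphe neurons also stays open and was not tested separately.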

How the results depend on the processing

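The fit without WT MMC replicate 3, SMA LMC replicate 2 and WT DRG replicate 1, each the lowest correlated array of its tissue, and the list without Smn1 were chosen after the data were seen; the other alternatives were planned. No list that passed and no followed gene that passed turned the direction of its test under any alternative run for it. Single genes were followed only where the naming rule took them from a whole comparison. Most genes that passed were not followed, nor were those named as list members alone, such as Perp and Mmp9 in MMC. The medians of some lists that passed crossed 0. Without SMA LMC replicate 2 that of the histones in LMC moved from -0.362 to 0.0211. Without SMA raphe replicate 2 that of the histones in the raphe moved from 0.26 to -0.0247. Named genes that passed kept their call in 1508 fits and lost it in 305, and lists in 344 and 137. Smn1 passed under every alternative run in each tissue and in the average. So did Gtse1 and Padi1 in MMC, C1ql2 and Pde1a in the raphe, and Gtse1 and Crip2 in the average. The p53 targets passed under all 13 alternatives in MMC (adjusted p 3.11e-17 to 0.00106), 13 in LMC (2.65e-14 to 0.0321) and 31 in the average (7.49e-19 to 3e-04), and oligodendrocyte markers between the columns under 13 (2.13e-20 to 0.00605). Crip2 in LMC did not pass with the deposited normalized values, with only the LMC arrays or with the replicate block (largest adjusted p 0.86), and Gad1 (0.284), Tnc (0.312) and Rassf4 (0.699) in the raphe and Tuft1 (0.301) and Bbox1 (0.476) in MMC failed under most. Between the columns, Dennd3 failed in 13 of 26 and Ranbp3l in 8 of 26. Signal over background limits what can be seen: genes below background in all groups of a comparison were not tested, and falls into background are lower bounds.

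Counts of passing genes moved as follows. No detection filter, which tests more genes, gave 50 in MMC and 193 between the columns in WT. The stricter filter, which drops Smn1 and other genes absent from a group by construction, gave 24 in MMC, 1 in LMC, 0 in DRG, 6 in the raphe, 2 in the average, 0 for MMC minus LMC, 1 for the F test and 145 between columns; at an unadjusted p under 0.05 limma counted 54 genes for the 0 in DRG. Testing all probes singly, which counts probes, gave 188 in MMC, 47 in the raphe, 13 in the average, 16 for the F test and 508 between columns. A threshold of 0.10 gave 257, 41, 9 and 758 in MMC, the raphe, MMC minus LMC and between columns. Array weights gave 36 in MMC, 4 in LMC, 43 in DRG, 62 in the raphe, 32 in the average, 4 for MMC minus LMC, 26 for the F test and 531 between columns; the cause was not tested. Without the lowest correlated array of each of MMC, LMC and DRG the counts were 351 in MMC, 2 in DRG, 46 in the raphe, 13 in the average, 18 for the F test and 722 between columns. With only the arrays compared, which leaves fewer arrays to estimate the spread and takes none of it from other tissues, they were 5 in MMC, 1 in LMC, 10 in the raphe, 0 for MMC minus LMC and 83 between columns. Median scaling gave 4 for MMC minus LMC, 4 for the F test and 489 between columns; it moved the median of all genes to -0.225 in DRG, 0.108 for MMC minus LMC and 0.332 between columns. No background correction gave 1 for MMC minus LMC and 3 for the F test, normalization within chips 1 and moderation without a trend 0 for MMC minus LMC, the deposited normalized values 37 in the raphe, and the mean of probes 11 for the F test; the cause of these was not tested. Normalization within chips was not run between columns. Of the 16 lists that passed between SMA and WT, 2 passed with an estimated correlation and 5 with fry, which passed 7 in all. Sizes depend on the values used: with the deposited normalized values, the differences of named genes that passed were in the median 0.356 of those printed in MMC (22 genes) and 0.285 in the raphe (19 genes), with Padi1 at 1.99 in MMC. The p53 median was then 0.489 in MMC, 0.234 in LMC and 0.131 in the average.

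The replicate block used the replicate numbers, which are not shown to pair arrays: no tissue had all 3 same-number pairs correlated above 0.1, and they ranged from -0.0919 to 0.323; in LMC alone each of the 3 arrays correlated best with its own number. With the block 50 genes passed in MMC, 1 in LMC, 8 in the raphe, 0 for MMC minus LMC, 2 for the F test and 24 between columns, where it uses up degrees of freedom.

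Leaving out 1 array left 2 in its group. The count ranged from 94 to 277 in MMC (277 without WT replicate 2, 182 without SMA replicate 2), 2 to 25 in LMC (25 without SMA replicate 3, 4 without SMA replicate 1) and 1 to 3 in DRG (3 without SMA replicate 3, 2 without WT replicate 1 or 2). It ranged from 7 to 37 in the raphe (7 without WT replicate 3, 11 without SMA replicate 3, 37 without SMA replicate 1) and 6 to 10 in the average (10 without SMA LMC replicate 1). For MMC minus LMC it ranged from 0 to 11: 0 without WT LMC replicate 1 or 2 or SMA LMC replicate 1, 1 without SMA MMC replicate 1 or WT LMC replicate 3, 4 without SMA LMC replicate 3, 7 without WT MMC replicate 1 or 3 or SMA MMC replicate 2, 9 without SMA MMC replicate 3 and 11 without WT MMC replicate 2. The F test ranged from 1 to 13: 1 without SMA MMC replicate 1, 2 without any 1 SMA DRG array, 3 without WT DRG replicate 1, 4 without WT LMC replicate 2 or WT DRG replicate 3, 11 without WT MMC replicate 3 and 13 without SMA LMC replicate 2. Between columns it ranged from 130 to 507 (130, 161 and 149 without WT LMC replicate 1, 2 and 3, 507 without WT MMC replicate 2), and for lists from 10 (without SMA LMC replicate 2) to 18. The p53 median ranged from 0.774 to 0.991 in MMC, 0.337 to 0.7 in LMC and 0.255 to 0.374 in the average. The correlation of MMC with LMC ranged from 0.0151 to 0.137, and reached an unadjusted p under 0.05 without WT MMC replicate 2 (0.095) or SMA LMC replicate 2 (0.137). List calls ended as follows, with medians. In MMC the histones did not pass without WT replicate 1 (0.524) or SMA replicate 2 (0.63), nor the neurofilament list without WT replicate 1 (-0.135), 2 (-0.234) or 3 (-0.178) or SMA replicate 2 (-0.159). In LMC, SMA replicate 2 ended the calls of the histones (0.0211), ribosomal proteins (0.0395), oxidative phosphorylation (0.00689), neurofilaments (-0.0641), cholesterol synthesis (-0.221) and immediate early genes (0.195). WT replicate 1 ended those of the histones (-0.275), oxidative phosphorylation (-0.145), neurofilaments (-0.168) and cholesterol synthesis (-0.234), and WT replicate 2 that of cholesterol synthesis (-0.133). WT replicate 3 ended those of oxidative phosphorylation (-0.101), immediate early genes (0.336) and microglia (0.386), SMA replicate 1 those of immediate early genes (0.0252) and microglia (0.782), and SMA replicate 3 those of the histones (-0.635) and cholesterol synthesis (-0.327). In the raphe, calls ended for the histones without WT (0.144) or SMA replicate 2 (-0.0247), axon injury genes without SMA replicate 1 (-0.0929) or 3 (-0.072), Hox genes without SMA replicate 2 (-0.208) or 3 (-0.105) and serotonergic markers without WT replicate 1 (0.41) or SMA replicate 3 (0.381). Between columns they ended for ion channels without WT MMC replicate 3 (0.4) or WT LMC replicate 1 (0.454) or 2 (0.474), complement genes without WT MMC replicate 3 (-0.405), cholesterol synthesis without WT LMC replicate 1 (0.491) or 2 (0.487), endothelial markers without WT LMC replicate 2 (-0.359) and inhibitory interneurons without WT MMC replicate 1 (-1.57) or 2 (-1.44) or WT LMC replicate 1 (-1.34) or 2 (-1.47). In the average, endothelial markers passed in 18 of 31 alternatives, mitotic genes in 21 and oxidative phosphorylation in 22. Of 22 named genes that passed in MMC, 7 did not pass without SMA replicate 3, 6 without SMA replicate 1 or WT replicate 1, 5 without WT replicate 3 and 3 without SMA replicate 2. Of 19 in the raphe, 14 did not pass without WT replicate 3 and 10 without SMA replicate 3.

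Apart from the medians of lists given above, all followed values that turned direction belong to differences that did not pass. With the deposited normalized values these were the correlation of LMC with DRG (0.00469) and Chat in MMC (-0.0217) and the average (-0.000324). Under median scaling they were Scn10a (-0.0391) and Mdm2 (-0.0877) in DRG, Ccng1 in the raphe (0.00741), and Smn1 (0.0711) and Mdm2 (0.0765) between columns. With the mean of probes they were Mdm2 in DRG (-0.137) and between columns (0.0561) and Ccng1 in the raphe (0.193). With array weights they were Chat in MMC (-0.501), the average (-0.0103) and MMC minus LMC (-0.396) and Ccng1 in the raphe (0.0200). Without the lowest correlated array of each of MMC, LMC and DRG they were Chat in MMC (-0.0896), Mdm2 for MMC minus LMC (-0.0154) and Smn1 between columns (0.192). The cause was not tested. Over the fits without 1 array, correlations ranged from -0.215 to 0.0495 for MMC with DRG, -0.0778 to 0.075 for LMC with DRG, -0.0233 to 0.0545 for LMC with raphe and -0.0134 to 0.117 for DRG with raphe. Chat ranged from -0.367 to 0.585 in MMC, -0.245 to 0.252 in LMC, -0.0835 to 0.337 in DRG, -0.00673 to 0.231 in the average and -0.325 to 0.626 for MMC minus LMC. Ccng1 ranged from -0.166 to 0.0873 in the raphe, Mdm2 from -0.21 to 0.421 for MMC minus LMC and -0.539 to 0.0922 between columns, and Smn1 from -0.414 to 0.192 between columns.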

Other observations

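Some further genes differed between the columns of WT mice. Nrn1, a protein that promotes the growth of neurites, was lower in LMC at -2.81 (adjusted p = 0.000694), as were Btg2 at -2.19 (adjusted p = 0.0224) and the survival gene Bcl2 at -1.08 (adjusted p = 0.0403). Higher in LMC were Ifi27, induced by interferon, at 2.24 (adjusted p = 8.36e-05), the peptide gene Nts at 2.34 (adjusted p = 0.0203), Myh8, a myosin of developing muscle, at 1.64 (adjusted p = 0.0164) and Map1b at 0.36 (adjusted p = 0.0349). These members of the gene lists were chosen after their values were seen. In the raphe the globin genes Hbb-b2 (-2.63) and Hba-a1 (-1.90) were lower in SMA when adjusted over their list alone, but not over all genes (adjusted p = 0.0569 and 0.222). Averaged over the 4 tissues they stood at -1.08 and -1.22, again past the threshold over the list alone and not over all genes (adjusted p = 0.316 and 0.142). Myh8 was higher in the SMA raphe on the same terms, at 1.67 (adjusted p = 0.0601 over all genes). Globin genes resemble each other, so their probes are not shown to be independent.

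Markers of sex were read on each array, and their naming was chosen after their values were seen. All 6 MMC arrays were above background for both Xist, made from an inactive X chromosome, and Eif2s3y on the Y chromosome. The levels of Xist were 10.7, 7.46 and 9.17 on WT MMC replicates 1 to 3 and 9.47, 7.77 and 10.5 on the SMA MMC replicates, and those of Eif2s3y 7.24, 8.54 and 6.25 and 7.34, 8.3 and 6.42 in the same order. WT DRG replicate 2 had both as well, at 9.52 and 8.41. Whether an array holds RNA of pooled animals is not given in the sources used here; if so, the SD in MMC is a spread between pools and not between animals. With sex as a covariate 104 genes passed in MMC in place of 114.

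Planned counts over other splits of the arrays bear on the main results. Within a tissue the 6 arrays make 10 splits, too few for a share under 0.05; the real split, 1 of the 10, gave 114 genes in MMC against at most 18 for the others, 2 against 0 in LMC, 1 against 0 in DRG, 23 against 1 in the raphe and 313 against 1 between the columns. For the average over tissues 100 relabellings were drawn. The real one, 1 of the 100, gave 6 genes and the highest of the others 2. The median of the p53 targets was 0.323 against at most 0.316 in either direction. No other labelling drawn reached either value, and with 100 labellings neither result excludes chance. For the p53 targets the real median lay only just above the highest of the others.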
